A study of Drosophila melanogaster with 6 samples.

How the data were processed

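RNA polymerase II (Pol II) was mapped by chromatin immunoprecipitation and sequencing in Drosophila embryos aged 2 to 4 h. Embryos of 3 genotypes were used, with 1 Pol II library and 1 input library each, so 6 libraries in all. Each library was placed in its group by its source label.

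The 6 deposited files hold no measurement column. Each line gives the chromosome, start and end of 1 aligned interval, with no strand. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 to genome build dm3. Mapping options, duplicate handling and filters are not given in the sources used here. In the gd7 files the intervals vary from 41 to 300 bp in the inputs and from 52 to 300 bp in the Pol II libraries, as sequenced fragments would. In the Toll10b files every interval is 40 bp in the input and 45 bp in the Pol II library, as single reads would be. Read format therefore goes with embryo type. In 5 of the 6 files some intervals lie on an added contig, which differs between genotypes. Stretches of 100 bp or more without reads in one genotype but covered in another were looked for at y, twi, pnr, sna and tup. They were found at y, twi and pnr and are called blind here. They are taken to be bases that the contig also holds, although the contig sequences were not at hand.

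Read counts were computed here from the deposited intervals, each placed at its middle. The transcript starts were those of the dm3 upstream sequences shipped with the R package Biostrings 2.70.1, which hold 26454 transcripts. Of these, 25847 (97.7%) were matched by accession to a symbol in a RefSeq gene table of another assembly (Release 6), used only for names. Starts of 12499 genes lie on the chromosome arms, and 3527 of these genes have a promoter window that overlaps that of another gene. A promoter window is the 501 bp centred on the start, taking for each gene the start with most Pol II reads over the 3 libraries. Gene ends on dm3 were not used here, so the gene body is a fixed stretch from 500 to 1500 bp after the start. In genes that end sooner, it runs past the gene end. Genes with another start in or near that stretch were left out, in place of the planned filter on gene length.

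Promoters and stretches were compared between Toll10b (1 library) and gd7 (2 libraries, which differ in their transgene) with limma 3.58.1 (voom, moderated test, 2-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The planned test was another count model. It was not run because such models were kept for deposited counts, although the counts made here would serve it. Library sizes were scaled by the trimmed mean of M values (TMM), computed on the promoter windows and used for the stretches too, as planned. By mistake the stretches were first scaled by their own factors, and the planned ones were restored after those results had been seen. A window was tested if it reached, in at least 1 library, the rate that 10 reads have in the median library, and 15 reads in all. The model has 1 residual degree of freedom. The prior degrees of freedom were infinite, so in effect 1 trend of the spread with read count, set by the gd7 pair, was used for all genes, and the lone Toll10b library was assumed to vary like that pair. Nothing in the labels says that the gd7 libraries come from separate collections, so p-values measure the spread between these libraries only. The ratio of promoter to stretch was tested as the interaction of region and embryo type in 1 limma model with a term for each library. The ratio printed per library is that of the read densities. It compares the start with the gene body only in genes that span the stretch.

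The 12 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry. The lists are dorsal ectoderm and amnioserosa, mesoderm, neuroectoderm, anterior-posterior segmentation, Hox, cellularization and early zygotic, ribosomal protein, heat shock, gut primordia, pole cell, hemocyte, and late neural and muscle genes. HLH54F (fixed under another spelling), fd19B and nos were not matched. Named genes also followed a fixed rule. They are gd, Tl, twi, sna, y, tup and pnr, and the 10 largest rises and 10 largest falls at promoters. Those 20 had to pass the test, move the same way against each gd7 library and be occupied where higher. Up to 4 members per list with the smallest p and up to 5 genes each way by smallest p for the stretch and the ratio complete the rule.

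Counts were simulated with the gd7 means, the real library sizes and 1 spread for all genes, estimated from the gd7 pair. All 3 libraries were drawn with that spread, and changed genes had over 100 expected reads. Here 86.33% of promoters and 88.67% of stretches changed by 2-fold were recovered over 3 runs, and 100% of those changed by 4-fold. The false share of calls was 3.16% over 12338 to 12348 promoters and 4.87% over 10373 to 10378 stretches. These shares take for granted that Toll10b varies like the gd7 pair. Neither another spread in Toll10b nor the read formats were simulated, so they are not error rates of the real calls.

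A promoter counted as occupied with at least 20 Pol II reads and at least 2-fold enrichment over its own input. Input was scaled by 5937 background bins of 10 kb, those with the lower Pol II to input ratio. The Pol II to input ratio in these bins was 0.337 in the gd7 library with the sna promoter, 0.317 in the other gd7 library and 0.248 in Toll10b. Transgene sequences were compared as ratios of read counts scaled to the background bins. Input ratios were scaled to the autosomal bins. Intervals of such ratios are exact binomial 95% intervals and cover counting error only. With 1 library per transgene there is no test between transgenes.

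The alternatives fixed before the data were examined were median-of-ratios factors, total reads, TMM factors from 10 kb bins, no filter, windows of 150 or 500 bp either side, 1 read per position, the most upstream start, an input offset, each gd7 library left out, and other limits for occupancy. Others were added after the data were seen, among them 1 end of each gd7 fragment and TMM factors from the stretches themselves. The 1-end setting cuts aligned gd7 fragments to at most 45 bp, the length of the Toll10b Pol II reads. It changes where gd7 reads are placed, not how they were aligned. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for counting, intervals and plots.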

Results

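Pol II occupancy was measured in embryos whose dorsoventral axis is altered. Embryos of mothers mutant for the protease gene gd (gd7) are taken to form mostly dorsal ectoderm. Toll10b embryos, in which the receptor Toll is always active, are taken to form mostly mesoderm, although neuroectoderm genes also held more Pol II there. The gd7 embryos carried a 25 kb twi transgene (a BAC) in which yellow replaces the twi coding region. In one gd7 genotype (twiBAC-snaPr-Yellow) the twi core promoter is also replaced by that of sna. In the other (twiBAC-Yellow) the twi promoter is kept. The Toll10b embryos carried a plasmid, M2, with a pnr enhancer, the tup promoter and yellow. The Pol II libraries held 25952616 intervals (twiBAC-snaPr-Yellow), 25643132 (twiBAC-Yellow) and 20550993 (Toll10b), and the inputs 25876072, 20595483 and 24013538. Repeated positions made up 33.33%, 40.9% and 36.27% of the Pol II libraries, against 2.43%, 2.72% and 15.86% of the inputs. Each genotype had 1 Pol II library, so values per genotype carry no replicate error.

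The input libraries were compared first, since extra copies of the twi region belong in the gd7 embryos alone. In the gd7 inputs the DNA around twi was over-represented from 18924001 to 18948000 on 2R (dm3), a span of 24 kb found by searching these data. Against the Toll10b input the ratio there was 1.443 (95% interval 1.393 to 1.494) in twiBAC-snaPr-Yellow and 1.495 (1.442 to 1.551) in twiBAC-Yellow. Outside that span the ratios were 1.028 and 1.009. These intervals do not allow for the search. When 1000 random autosomal regions of 70 kb were searched the same way, a comparison added after the data were seen, 2 held a gd7 excess as marked as that at twi. Within the span, the twi stretch from 500 to 1500 bp after the start, part of the gene that yellow replaces in the transgene, had input ratios of Toll10b to gd7 of 0.928 (0.801 to 1.074) and 0.971 (0.83 to 1.137).

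**Figure D1:**
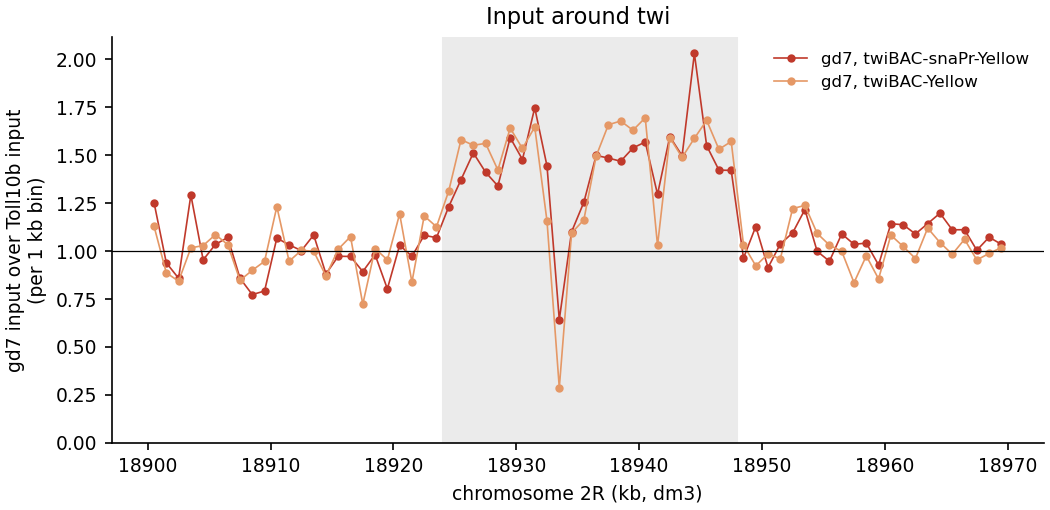
Input reads per 1 kb bin around twi on 2R (x axis, kb, dm3), as the ratio of each gd7 input to the Toll10b input after scaling to autosomal bins (y axis). Both gd7 lines lie above 1 in the shaded span of 24 kb and dip at twi itself. There, parts of the genome are blind in gd7, and yellow replaces the twi coding region in the transgene.

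Similar numbers of promoters held Pol II in each genotype. Of 12499 promoters, 8241 (65.93%) were occupied in twiBAC-snaPr-Yellow, 8559 (68.48%) in twiBAC-Yellow and 8335 (66.69%) in Toll10b. All 3 libraries shared 7832 of them. A further 263 were occupied in both gd7 libraries and not in Toll10b, 253 in Toll10b and in neither gd7 library, and 610 in 1 gd7 library only. Genes of the other tissue were rarely without Pol II at the start: 27 of 28 mesoderm promoters and 16 of 17 neuroectoderm promoters were occupied in both gd7 libraries, and all 20 dorsal ectoderm promoters were occupied in Toll10b. Of the occupied promoters with a usable downstream stretch, 21.59%, 18.84% and 20.71% had a stretch below the same limits in twiBAC-snaPr-Yellow, twiBAC-Yellow and Toll10b. A stretch enriched by under 2-fold is among these. In gd7 these included 8 mesoderm genes whose stretch was occupied in Toll10b (twi, htl, tin, stumps, wntD, NetA, bap and ltl) and 5 neuroectoderm genes (sog, vnd, sim, ths and Dr). The reverse was not seen: all 17 dorsal ectoderm genes with a usable stretch were occupied over it in Toll10b. The blind part of the twi window in gd7 applies to twi here as well. The gd7 transgenes can also add reads around the twi start, but not over the coding region that yellow replaces. The median enrichment over input at occupied promoters differed between libraries, at 10.74, 15.19 and 11.77.

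Pol II at promoters was higher in Toll10b at 374 genes and lower at 423, of 12378 tested (limma, adjusted p under 0.05). Among the largest rises were the serotonin receptor gene 5-HT1A, at log2 fold change 3.04 ± 0.20 (SE; adjusted p = 2.2e-48 by limma; 146 and 180 reads in gd7 against 1051), Rpn12R at 3.63 ± 0.40 and hll at 2.60 ± 0.20. Muscle actin Act57B (2.17 ± 0.41), the Mef2 inhibitor gene Him (2.15 ± 0.37), wwk (2.12 ± 0.25), CG12725 (2.76 ± 0.63), CG31709 (2.11 ± 0.43) and CG43231 (2.10 ± 0.42) were in the same group. The mesodermal regulator twi (start at 18933849 on 2R) rose by 2.52 ± 0.19, but part of its window is blind in gd7 (18933476 to 18933743 in twiBAC-Yellow, 18933522 to 18933643 in twiBAC-snaPr-Yellow). Against the single gd7 libraries its change was 1.85 and 3.18. The Rpn12R start (15035670 on 3L) lies near that of ind (15037024), a neuroectoderm list gene whose promoter also rose (0.77). The CG31709 start (9579638 on 2L) lies downstream of that of gcm (9581745), whose stretch rose. Pol II of these neighbours may add to both windows, which was not tested. The calls for Act57B, CG12725, CG31709 and CG43231, all with few reads, ended with an input offset. Input in their windows differed by log2 0.113, 0.222, 0.053 and -0.059 in that order.

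Among the largest falls, 3 promoters had at least 75 input reads in every library, with scaled input under 2-fold apart between embryo types. They were CG2269 (start at 5972774 on 2R; 3076 and 3695 reads in gd7 against 385; log2 fold change -2.78 ± 0.19; adjusted p = 7.5e-45 by limma), the odorant binding protein gene Obp56a (-2.69 ± 0.42) and the proteasome subunit gene Prosalpha6T (-2.76 ± 0.42). The value for Prosalpha6T turned to 0.53 with windows of 150 bp either side. Its stretch was higher in Toll10b (0.58 ± 0.15) and shares 380 bp with that of Mabi. The histone gene His1:CG33834 (362 and 492 Pol II reads against 3) had 3, 3 and 2 input reads, too few to compare. At the other 6 (CG18278, CG32500, CG32857, CG33502, Hsp70Ba and sordd2) the Toll10b input held at most 12 reads and was over 2-fold below that of gd7, so that reads missing there cannot be told from Pol II missing there. The windows of CG32500, CG32857 and CG33502 overlap, and Hsp70Ba and His1:CG33834 belong to families of near-identical genes. Hsp70Ba, for example, had 989 and 1293 Pol II reads in gd7 against 34, but also 102 and 82 input reads against 12. The gd promoter itself was lower in Toll10b (-1.93 ± 0.19; adjusted p = 7.2e-21; 1010 and 1102 reads against 217), as was that of pnr, a regulator of dorsal ectoderm (-1.28 ± 0.18). The Tl promoter did not pass (-0.04 ± 0.20; adjusted p = 0.97). With factors from 10 kb bins the calls numbered 127 higher and 167 lower, and 220 of the 797 were kept, while the input offset gave 76 and 94 and kept 165. With factors from occupied promoters only, an alternative chosen after seeing the data, the calls split into 556 higher and 407 lower.

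The dorsoventral lists stood apart at promoters. Of 28 mesoderm promoters, 14 rose (16 rose and 1 fell adjusted over the list alone). Cyp310a1 rose by 1.59 ± 0.18, the Wnt ligand gene wntD by 1.51 ± 0.19 and the Netrin gene NetA by 1.39 ± 0.19. Of 17 neuroectoderm promoters, 7 rose (8 rose and 1 fell adjusted over the list alone), among them the FGF ligand gene ths (1.71 ± 0.18), vnd (1.66 ± 0.19), SoxN (1.59 ± 0.19) and sog, which encodes a Dpp antagonist (1.35 ± 0.18). With the most upstream start the values of ths and sog were -0.04 and 0.31, and neither passed. Of 20 dorsal ectoderm promoters, 14 fell (16 adjusted over the list alone), with zen2 at -2.16 ± 0.24, C15 at -1.73 ± 0.21, Doc2 at -1.51 ± 0.18 and tup at -0.92 ± 0.20. The tup window held 193 and 155 input reads in gd7 against 123 in Toll10b, whose plasmid carries a tup promoter, and the tup call ended with the input offset (-0.34). Camera gave adjusted p of 1.34e-21, 9.21e-15 and 2.56e-29 for the 3 lists in that order. Each list had an adjusted p of 0.475 with an estimated correlation. The rotation test fry (limma) gave unadjusted p of 0.0657, 0.0762 and 0.06. The snail gene sna, a mesoderm regulator that starts at 15478269 on 2L, rose by 0.74 ± 0.21 at its promoter (adjusted p = 0.0113 by limma; 1830 and 2090 reads in gd7 against 2569). That call ended with total reads, factors from 10 kb bins, the narrower window, the input offset, and 1 fragment end with 1 read per position. The median over all promoters was -0.01 in the main setting, -0.03 with total reads and -0.05 with 10 kb bins. Input at sna differed by log2 0.102. With 1 read per position and whole fragments the values of sna and SoxN turned to -1.20 and -0.11, and the means of the mesoderm and neuroectoderm lists to -0.0942 and -0.403.

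Other lists changed at promoters too. Cellularization and early zygotic genes were lower (camera adjusted p = 4.99e-04; adjusted p = 0.475 with an estimated correlation), and 2 of 10 fell, zen2, which is also on the dorsal list, and nullo (-1.07 ± 0.20). Heat shock genes were lower (adjusted p = 0.00112; adjusted p = 0.475 with an estimated correlation), with 4 of 10 fallen, Hsp27 (-1.72 ± 0.22), Hsp22 (-0.85 ± 0.19), Hsp83 (-0.71 ± 0.17) and Hsp23 (-0.71 ± 0.21). Late neural and muscle genes were higher as a list (adjusted p = 0.044; adjusted p = 0.611 with an estimated correlation), although of 10 promoters 1 fell, that of the synaptic gene brp (-1.09 ± 0.28; 2 rose and 1 fell adjusted over the list alone). Of these 10 promoters, 3 were occupied in both gd7 libraries and 6 in Toll10b. The list did not pass with windows of 500 bp either side, 1 read per position or factors from occupied promoters. Anterior-posterior segmentation (oc up by 0.70 ± 0.19 and bcd at -1.37 ± 0.43, of 24), Hox (pb at -1.23 ± 0.30, of 8), gut primordia (cad at -0.61 ± 0.18, of 8), pole cell (aub at -1.62 ± 0.30, of 6) and hemocyte lists (Pvr at -0.63 ± 0.17, of 8) did not pass as lists (adjusted p = 0.922, 0.184, 0.93, 0.104 and 0.349). The list of 91 ribosomal protein promoters did not pass either (0.299). The segmentation list had a median and mean of -0.03 although camera placed it higher, and the gut list a median of 0.01 and mean of 0.03 although camera placed it lower.

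Past the start, genes of the same tissues differed more. Pol II over the sna stretch was 26.1-fold higher in Toll10b (log2 fold change 4.71 ± 0.17; adjusted p = 5.01e-159 by limma), with 8396 reads against 378 and 440. Over twi it was higher by 4.90 ± 0.23, with 2864 reads against 141 and 105, over DNA whose input ratio is given above. The other rises with the smallest p were brk, a repressor of Dpp targets (4.26 ± 0.22), hll (3.38 ± 0.16) and the neuroectodermal regulator SoxN (3.14 ± 0.15). The falls with the smallest p were the sugar transporter gene sut4 (-2.71 ± 0.14), CG2269 (-2.63 ± 0.14), whose stretch shares 795 bp with that of sut4 and so mostly the same reads, zen2 (-2.36 ± 0.16), CG13653 (-2.26 ± 0.14) and the TNF ligand gene egr (-2.14 ± 0.14). The dorsal regulators tup (-1.75 ± 0.15), ush (-1.87 ± 0.14) and pnr (-1.59 ± 0.15) were lower too. In all, 1042 stretches were higher and 303 lower in Toll10b, of 10383 tested (limma), and 76 and 39 of these share over 500 bp with the stretch of another gene. The number of higher stretches depends on the scaling: the median of all stretches was 0.09, and with factors from the stretches themselves it was -0.03 with 295 higher and 375 lower, while total reads gave 573 and 262 and 10 kb bins 180 and 168. The stretches were first scaled by their own factors by mistake. The planned factors were restored after those counts had been seen, and the others kept as an alternative chosen after seeing the data. The value of y over its stretch (1.98) cannot be read between genotypes, since 406 bp of it are blind in twiBAC-snaPr-Yellow and 457 bp in twiBAC-Yellow.

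By list, 22 of 26 mesoderm stretches rose (23 adjusted over the list alone; median log2 fold change 1.66), among them wntD (3.14 ± 0.25; 432 bp shared with the stretch of Osi22) and NetA (3.35 ± 0.28). Of 16 neuroectoderm stretches 12 rose (12 adjusted over the list alone; median 1.30), with sog at 4.72 ± 0.46 and vnd at 3.88 ± 0.44. Of 17 dorsal ectoderm stretches 15 fell (15 adjusted over the list alone; median -1.37). Camera gave adjusted p of 1.97e-74, 1.75e-36 and 7.61e-70 for these lists, and the adjusted p was 0.251 for each with an estimated correlation. The rotation test fry (limma) gave unadjusted p of 0.0346, 0.00816 and 0.0215. Segmentation genes had 13 of 22 stretches higher (13 adjusted over the list alone; adjusted p = 6.24e-17; adjusted p = 0.393 with an estimated correlation). Among them were gsb (2.70 ± 0.17), a member named by the ratio below, and slp1 (1.45 ± 0.16) and ems (1.41 ± 0.14), chosen after their values were seen. Ribosomal protein genes were higher as a list, with 29 of 73 up and 1 down (36 and 1 adjusted over the list alone; adjusted p = 5.98e-09; adjusted p = 0.251 with an estimated correlation), but with factors from the stretches themselves, chosen after seeing the data, the mean change fell from 0.32 to 0.20. Cellularization genes were lower with 5 of 9 down (5 adjusted over the list alone; adjusted p = 3.06e-11; adjusted p = 0.355 with an estimated correlation), nullo at -1.11 ± 0.13 and term at -1.87 ± 0.22. Heat shock genes were lower with 2 of 6 down, Hsp27 and Hsp23 (adjusted p = 0.0299; adjusted p = 0.425 with an estimated correlation). The Hox (adjusted p = 0.42), gut primordia (0.42), pole cell (0.129), hemocyte (0.42) and late differentiation (0.882) lists did not pass. The last 2 had medians of 0.16 and 0.09 and means of 0.11 and 0.22 although camera placed them lower. The glial and hemocyte regulator gcm rose (1.98 ± 0.19). Gene lengths were not checked. In any list, that of ribosomal protein genes included, the stretch can therefore run past the end of short genes.

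**Figure D2:**
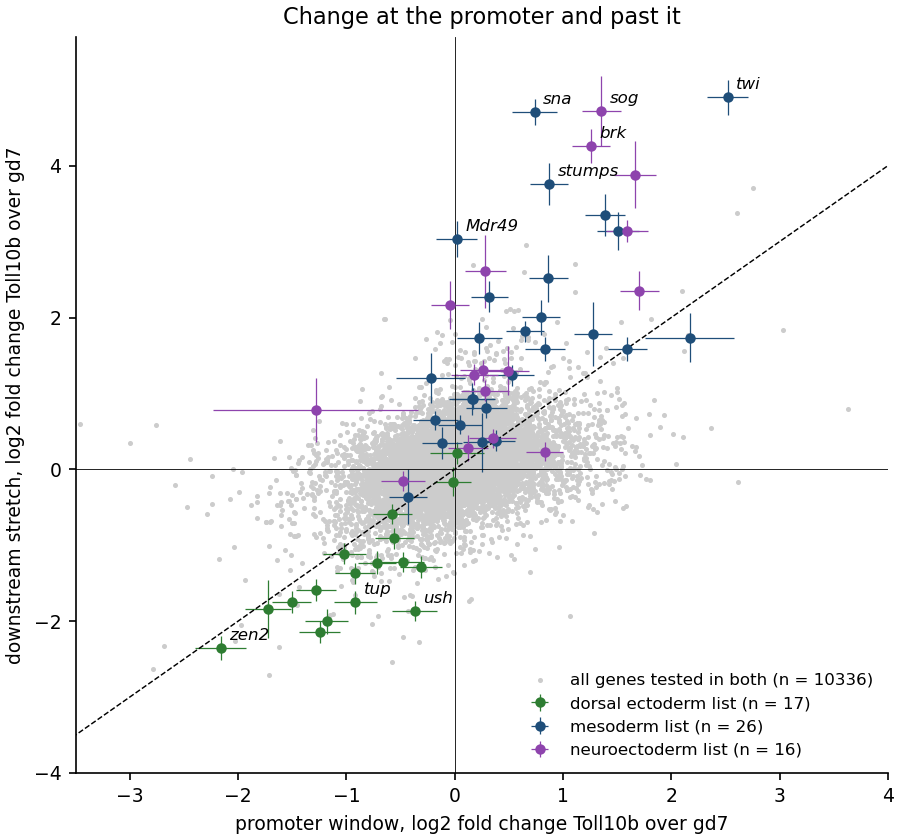
Log2 fold change of Toll10b over gd7 at the promoter window (x axis) and over the stretch 500 to 1500 bp after the start (y axis) for 10336 genes, with bars of 1 SE for members of 3 lists; a few genes with larger falls lie outside the axes. Mesoderm and neuroectoderm genes such as sna (0.74 at the promoter, 4.71 past it) lie above the dashed line of equal change, and most dorsal ectoderm genes lie below it.

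The ratio of promoter to stretch density, an index of how much Pol II stays near the start, changed at 425 of 10345 genes, 102 higher and 323 lower in Toll10b (limma interaction). The ratio of sna was 9.67 and 9.49 in the gd7 libraries and 0.61 in Toll10b, a log2 change of -3.97 ± 0.14 (adjusted p = 8.49e-163 by limma). Mdr49, whose promoter did not change detectably (0.02 ± 0.19), went from 21.2 and 27.6 to 2.98. The values were 8.85 and 5.76 against 0.88 for brk, and 8.24 and 12.3 against 1.75 for gsb. The ratio of bnb also fell (-1.19). In the other direction, the ratio of ush went from 2.15 and 2.27 in gd7 to 6.24 in Toll10b, and those of Dtg (1.33 ± 0.12), bun (1.29 ± 0.15), CG12420 (1.28 ± 0.16; 974 bp of its stretch shared with CG12817) and the Dpp pathway regulator shn (1.22 ± 0.16) rose. The ratio of tup was 3.70 and 4.32 in gd7 and 7.14 in Toll10b (0.83 ± 0.19; adjusted p = 8.03e-04), with the limits of its promoter window given above. The median change over all genes was -0.10, and with separate factors for each region, chosen after seeing the data, 158 genes were higher and 322 lower. With 1 end of each gd7 fragment, also chosen after seeing the data, 62 were higher and 137 lower, while 1 read per position turned the values of Dtg and tup to -0.47 and -0.69.

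**Figure D3:**
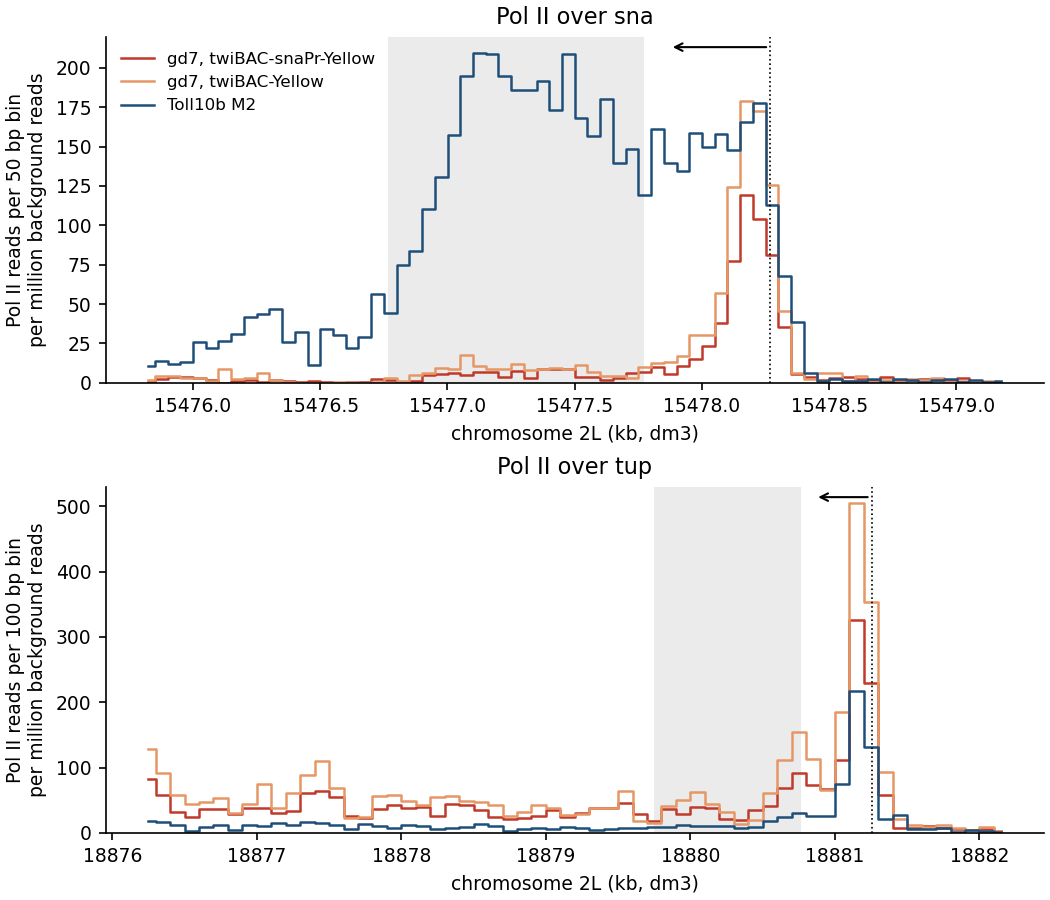
Pol II reads per bin, scaled to background reads (y axes), over sna (50 bp bins) and tup (100 bp bins) on 2L (x axes, kb, dm3) in the 3 libraries; dotted lines mark starts, arrows the direction of transcription and shading the stretch tested. Over sna the gd7 lines are high near the start only, where reads were 1830 and 2090, while Toll10b stays high through the shaded stretch with 8396 reads.

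The transgenes were compared to see how Pol II sits on yellow behind the sna and the twi promoter in the same embryo type. Over yellow past its blind part (251642 to 254942 on X), Pol II was 2.12 times as high in twiBAC-snaPr-Yellow as in twiBAC-Yellow (1645 and 579 reads; 95% interval 1.924 to 2.331), scaled to background. The 5′ part of yellow (250742 to 250992) gave 2.31 (1.848 to 2.894; 331 and 107 reads), and the 3′ part of twi that the transgene keeps next to yellow (18935799 to 18936499 on 2R) gave 1.97 (1.658 to 2.356). The replaced twi stretch gave an interval of 0.772 to 1.301, and the flanks of yellow 1.35 (1.072 to 1.707) upstream and 1.08 (0.853 to 1.38) downstream. Input over yellow differed by a ratio of 0.964 (0.891 to 1.044). Over its own input, Pol II on yellow was enriched 3.55-fold in twiBAC-snaPr-Yellow, 1.61-fold in twiBAC-Yellow and 2.77-fold in Toll10b, and the native y gene on X adds to each value. These parts were chosen after the data were seen, and 1 library per transgene allows no test.

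**Figure D4:**
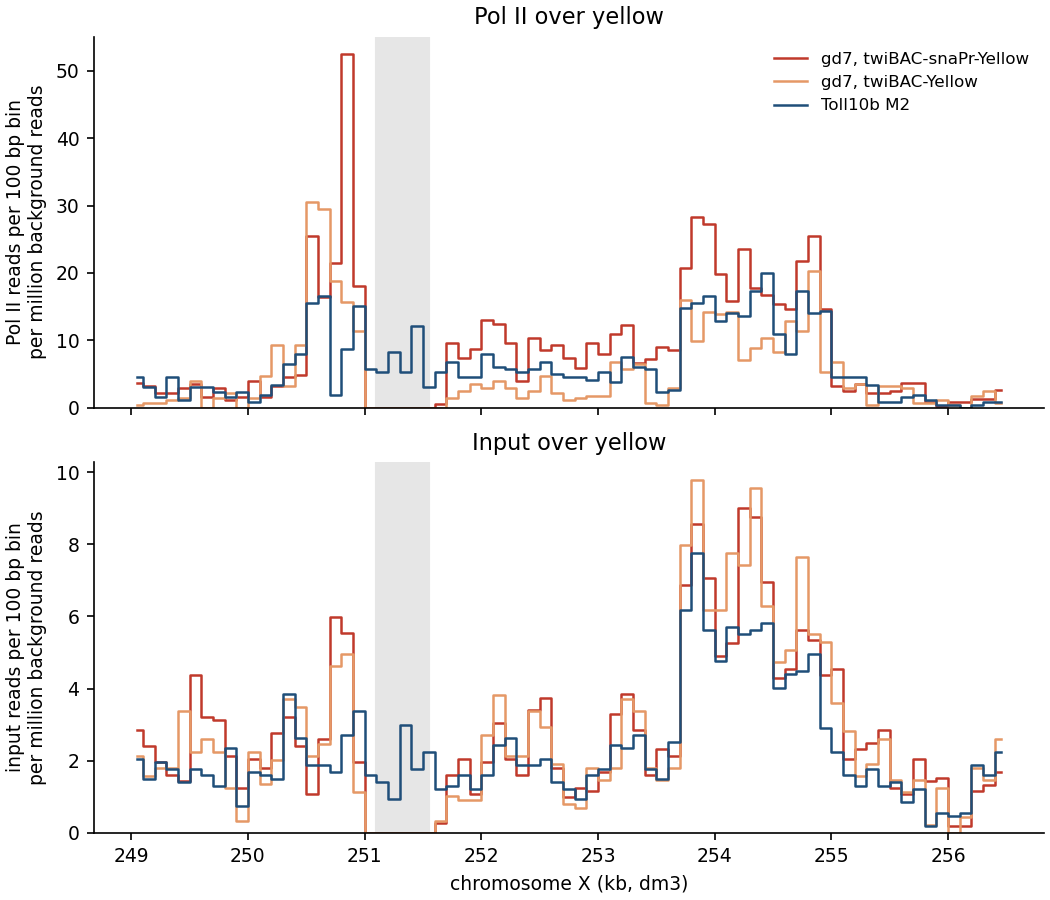
Pol II and input reads per 100 bp bin, scaled to background reads (y axes), over yellow on X (x axis, kb, dm3) in the 3 libraries; shading marks the stretch that is blind in gd7. Past the shading the twiBAC-snaPr-Yellow Pol II line runs above that of twiBAC-Yellow (1645 against 579 reads), while their inputs run together.

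Some reads lay on the added contigs, which differ between genotypes. The contig of twiBAC-snaPr-Yellow held 409 Pol II and 20 input reads, an enrichment of 60.7-fold (38.8 to 100.4), and that of the Toll10b plasmid 310 and 27 reads, 46.3-fold (31.2 to 71.4). The contig of twiBAC-Yellow held 4 Pol II reads and no input read, so no enrichment was computed for it. Which bases of the contigs are unique is not known here, so their counts cannot be compared with each other. Intervals here and above cover counting error only.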

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

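Pol II signal also appeared on unplaced and heterochromatic contigs, which no comparison of the report uses. What drew attention was Pol II at 4-fold or more over the input of the same genotype in bins of 1 kb, with at least 20 reads. There were 599 such bins in gd7 twiBAC-snaPr-Yellow (of 27204 with input reads), 794 in gd7 twiBAC-Yellow (of 26416) and 266 in Toll10b (of 16162), and 170 bins met this in all 3 libraries. The shares were 2.2%, 3.01% and 1.65%. The Toll10b library consists of shorter, single reads, and no explanation was tested.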

How the results depend on the processing

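The settings with 1 end of each gd7 fragment, factors from occupied promoters, from the stretches or per region, limma-trend and windows with input within 1.5-fold were chosen after the result was seen. Each result was compared once per alternative, and these comparisons were counted. For counts, lists and transgene values, 329 comparisons held and 6 turned in sign. For single genes, the flanks of yellow and the replaced twi stretch, 1989 comparisons held and 15 turned. The others changed in size or passed in only 1 of the settings compared. Most of the single genes were named for a small p or a large change in these same data. The settings also reuse the same reads, so the share that held is no measure of how the calls at large hold. Of all promoter calls far fewer stayed in some settings, as given next. The planned negative-binomial tests were not run, although the counts made here would serve them. Placing reads at an unmoved end was not possible, since the files hold no strand. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.

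Promoter calls numbered 127 higher and 167 lower with factors from 10 kb bins (220 of the 797 stayed), 76 and 94 with the input offset (165 stayed), and 321 and 369 with 1 end and 1 read per position (527 stayed). The higher share of promoter calls was 46.9%, against 57.7% with factors from occupied promoters and 36.7% with limma-trend. Stretch calls higher in Toll10b numbered 573 with total reads, 180 (168 lower) with 10 kb bins and 295 with factors from the stretches, where 555 of 1345 calls stayed. Their higher share of 77.5% became 68.6%, 51.7% and 44%. For the ratio, 1 end gave 62 higher and 137 lower, and factors per region 158 higher. Leaving out 1 gd7 library gave 459 to 501 promoters and 317 to 402 stretches over 2-fold, against 421 and 282. Total reads gave transgene ratios of 3.057 (yellow 5′ part), 2.807 (rest of yellow) and 2.616 (twi 3′ part). The same scaling gave 1.79 at the upstream flank of yellow, 1.436 at the downstream flank and 1.327 over the replaced twi stretch.

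Keeping 1 read per position turned the most values in sign, and its construction shows why: a window holds at most 1 single read per base but many more distinct fragments (sna in Toll10b went from 2569 to 388 reads). It gave 1424 higher and 2191 lower promoters, 3643 higher stretches and 2717 lower ratios. List means at promoters turned for mesoderm (-0.0942), neuroectoderm (-0.403), segmentation (-1.03) and ribosomal proteins (-0.630), and over stretches for segmentation (-0.181) and gut (-0.0814). The pole cell list passed (-0.641), and late differentiation (0.871) and heat shock stretches (-0.0533) did not. Promoter values turned for Antp (-0.95), Mdr49 (-0.90), RpL36A (-0.87), SoxN (-0.11), gsb (-0.58), hkb (-0.48), oc (-0.27), shn (-1.04) and sna (-1.20), stretch values for bnb (-2.08) and kni (-0.40), and ratios for Dtg (-0.47) and tup (-0.69).

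In other settings, Prosalpha6T turned with the 150 bp window (0.53) and ths with the most upstream start (-0.039). The Hox list passed with the 500 bp window (-0.303), the late list did not with that window (0.585) or with factors from occupied promoters (0.706), and heat shock did not with limma-trend (-0.394). Except for 1 read per position, the cause was not tested.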

Other observations

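The tests in this part were chosen after the results they bear on were seen, except those of chromosome arms and the counts of libraries. Neighbouring promoters on 2R fell together in Toll10b. The starts of egr (5965870), CG2269 (5972774) and sut4 (5974568) lie within 10 kb of each other, and all 3 were lower in Toll10b at the promoter (-1.25, -2.78 and -1.71). The stretch values were -2.14, -2.63 and -2.71, but CG2269 and sut4 converge and their stretches share 795 bp, so those 2 are mostly 1 signal. The sut4 promoter window also lies downstream of the CG2269 start. Its density was 0.209 and 0.161 of that over the sut4 stretch in gd7 and 0.364 in Toll10b. It may therefore hold Pol II of CG2269 too, which was not tested. The egr gene is on the dorsal ectoderm list and the others are on none. Between the gd7 libraries, 101 of 8958 promoters occupied in any library differed by 2-fold or more, against 459 and 501 between Toll10b and each of them. The gd7 libraries share both embryo type and read format, so these counts do not separate the 2. Most of the 101 were higher in twiBAC-snaPr-Yellow.

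The genes of the dorsoventral lists changed more past the start than at it. Over 41 mesoderm and neuroectoderm genes the median of the stretch change minus the promoter change was 0.824 on the log2 scale, and 37 of the 41 lay above 0. The central 95% of 10000 random lists of like read count ran from -0.027 to 0.256. Over 17 dorsal ectoderm genes the median was -0.353, 16 of them below 0, against -0.113 to 0.328 for random lists. Genes are not replicates, and 1 Toll10b library was measured. Segmentation genes went the same way as mesoderm genes (0.533; random lists -0.086 to 0.292), as did the 6 Hox genes (0.509; -0.207 to 0.466), and ribosomal protein genes did by less (0.299; 0.017 to 0.223), so the shift is not limited to the dorsoventral lists.

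The 797 promoters called between embryo types were weighed against the read formats. Input differed over 2-fold in the direction of the call at 12 of them (1.51%), which argues against mapping differences of that size for most calls. Among all 12378 tested promoters, input was over 2-fold apart in either direction at 45. A large share of the calls could therefore not have shown it, and the 12 are more than their part of the 45. Calls began at a log2 fold change of 0.508, so this bound cannot exclude smaller ones. Of the calls, 752 lay in windows with input within 1.5-fold, which 12139 windows had. When only such windows were tested, 748 of the 752 stayed. That test reuses the same counts, so nearly all had to stay and it cannot weigh the read formats. With the input offset 165 of the 797 stayed, so smaller mapping differences remain open. Placing whole fragments against single reads does not account for the set either, since 95% of the calls stayed with 1 end of each gd7 fragment. For the 12 promoters, among them Hsp70Ba and twi, Pol II exceeded the input change by a median of 1.028 with a range from -0.451 to 3.16. Mapping and a real difference therefore cannot be told apart for these windows as a set. At DNAlig3, rno, CG3176 and Rab3GAP1 input changed more than Pol II, and at the rest Pol II changed more. The twi window is partly blind in gd7. Past it, the twi stretch had input ratios of Toll10b to gd7 of 0.928 and 0.971, with 2864 Pol II reads against 141 and 105. With 1 Toll10b Pol II library, a difference of the lone Toll10b library stays open for all calls, as does the embryo type itself.

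Pol II over yellow was higher behind the sna promoter than behind the twi promoter (2.117-fold). A higher background in that library is argued against by other genes with a like count: the highest of 5092 reached 1.544, with a median of 0.735. More copies of yellow or better mapping would raise the input ratio too, which was 0.964. A difference of single libraries or insertions cannot be excluded with 1 library of that transgene. An effect of the promoter, the difference the design names, stays open with it.

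Calls outside the lists could come from unlike genetic backgrounds, such as a different X chromosome in gd7 embryos or a different arm 3R, where Tl lies, in Toll10b embryos. Of 739 such calls among 12100 promoters with input no more than 2-fold apart, 126 lay on the X, with an odds ratio of 1.133 against the other arms (0.922 to 1.385; Fisher's exact p = 0.227, adjusted p = 0.284 over 5 arms). On 3R there were 161, an odds ratio of 0.832 (0.691 to 0.998; Fisher's exact p = 0.0481, adjusted p = 0.12). The largest ratio was that of 2R, for which no explanation was named beforehand: 175 calls, an odds ratio of 1.256 (1.048 to 1.501; Fisher's exact p = 0.0119, adjusted p = 0.0597). The intervals of the X and 3R lie under 1.5, the bound set beforehand, which argues against a large excess on those arms and leaves smaller effects and single loci open.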
